A study of Oryza sativa with 44 samples.

How the data were processed

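RNA was measured in 44 libraries of rice seedlings grown for 2 weeks, and the labels do not name the organ. Per the labels' protocols, total RNA was extracted with a plant RNA kit, treated with DNase, fragmented and made into paired-end libraries with a NEBNext Ultra kit. Per the submitters' processing notes, HISAT2 and featureCounts were used with the genome build IRGSP-1.0, and their versions and settings are not given in the sources used here. Whether the counting used strand is likewise not given, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. The authors deposited a table of whole-number counts per gene, with no normalization, and a table of FPKM. The deposited FPKM equal the count times a constant divided by the column total and by a fixed whole-number gene length, so they add the gene length and no other information. Each table also holds 40 columns with no sample here, which were not used.

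The count table has 58089 rows, of which 55801 carry an MSU locus ID, 2103 an ID with a running number and no locus, and 185 an ID of an unplaced sequence. No row lacks a gene ID. The files do not pair IDs with names, and the reference table of gene names (assembly ASM3414082v1) matched 1 ID through a synonym. The 30 gene lists fixed before the data were examined use another kind of locus ID and descriptions. None of their loci could be paired with the count table, so the list tests, the levels of the YTH family genes and the tissue markers were not run. Chromosome and order of a gene come only from its locus ID, and no coordinates are given.

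Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM normalization, filterByExpr, robust dispersion estimates and the two-sided quasi-likelihood test, with 1 fit for the 33 NIP libraries (27584 genes), 1 for the 11 DJ libraries (26925 genes) and 1 for all 44 libraries (28833 genes) for the wild types against each other. Each line was compared with the wild type of its labelled background. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum, and counts with a minimum of 2-fold are given as well. The biological coefficient of variation between replicates was 4.6% in the NIP fit and 5.39% in the DJ fit. Group means are of CPM, scaled by the library total. The standard error of a log2 fold change is its size divided by the square root of the F statistic. A fold against a group with no counts is a lower bound that takes 3 counts over the group as the floor. With 1 to 3 counts the ratio is given with its exact 95% interval. Intervals and floors cover counting error only.

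The rule for named genes was fixed before the data were examined. It took, per comparison, the genes with the largest fitted log2 fold changes each way. The rule asked for an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups. For genes called in several NIP lines it ranked by the number of lines and then by the mean log2 fold change. As no names are paired with the IDs, at most 2 IDs that rose and 2 that fell are printed per comparison. These are the first of the rule's 8 genes each way that have an MSU locus ID. Features without a locus were tested and counted like all others, and 3 that ranked first are described without an ID. Loci outside this rule are named as picked after their values were seen. No replicates were collapsed, since all 43 pairs of replicate libraries differed by more than counting noise: the chi-square per degree of freedom ranged from 1.58 to 120, with a median of 2.4.

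The test was first run on simulated data. All 33 NIP libraries were drawn from their group means and the fitted dispersions, with osythdf3b set to the means of NIP (27651 genes). With 50 genes changed in osythdf3b at each size, edgeR recovered 44% of genes changed 1.2-fold, 80% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. In the 11 DJ libraries, drawn the same way with osythdf2a set to the means of DJ (26319 genes), the shares were 22%, 72%, 92% and 100%. Unchanged genes called were 7 in the first and 14 in the second simulation. The changed genes, as many raised as lowered, had at least 1 CPM in the control. All other genes were unchanged between the 2 groups compared, while the other groups of the fit kept their own means. The shares therefore do not cover data in which most genes differ and the scaling matters, as here. The window scan used fixed windows of 50 measured loci, with a gene taken as private to a group at 2-fold outside the means of all others on log2(CPM + 0.1) and at least 1 CPM, and a threshold of 0.01 on the adjusted p. It found a planted segment.

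Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, only the 2 groups compared, the replicate number as a block, the 2-fold minimum, the other lines as reference, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), and each replicate left out in turn. Groups as units, a correction for gene length, library totals in place of TMM in edgeR, the removal of a shared component, the thinning of libraries and other choices for the window scan were added later. Unchanged groups against shared controls were simulated 3 times from the control means and the fitted dispersions. Python 3.11.15 with scipy was used for the gene classes and windows.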

Results

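RNA was sequenced from 44 libraries of rice (Oryza sativa) seedlings raised for 2 weeks in nutrient solution. The libraries fall into 15 groups. Both controls are wild type plants, NIP and DJ. The other groups are 10 CRISPR knockout lines, 2 RNAi knockdown lines and 1 overexpression line of genes of the YTH family, whose proteins bind methylated adenosines in RNA. The lines osythdf1a, osythdf2a and osythdf3a were labelled as DJ, and the other 10 lines as NIP. Every group had 3 libraries except osythdf2a, which had 2. The series was set up to ask how loss of YTH family genes changes gene expression. Library totals ranged from 13541543 to 24099581 counts, so that a gene at 1 CPM (the usual depth-scaled read count) rested on more than 10 counts in each library. The labels do not say which organ was taken. The series text calls the replicates biological, and the p-values measure the spread between these libraries only.

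The deposited tables list 58089 features by locus ID and the files do not pair these IDs with gene names, so genes are given by ID and the transcripts of the targeted YTH genes were not analysed here. A single ID matched the reference table of gene names, LOC_Os01g19850, listed there with the synonym OsCCC2, a name of a cation chloride cotransporter. Its level was 0.433 ± 0.17 CPM (SD, n = 3) in NIP and 1.96 ± 0.35 CPM (SD, n = 3) in DJ. It rose most in osythdf1b, to 2.72 ± 0.57 CPM (log2 fold change 2.40, SE 0.28, adjusted p = 1.3e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It fell in osythdf1a to 0.448 ± 0.11 CPM, with a log2 fold change of -1.86 (SE 0.32, adjusted p = 9.4e-07 by the same edgeR test with Benjamini-Hochberg adjustment). It fell in osythdf3a as well (log2 fold change -1.35, SE 0.30, adjusted p = 9.4e-05) and rose in osythdf2a (0.63, SE 0.25, adjusted p = 0.028), by the same edgeR test with Benjamini-Hochberg adjustment. Of the 10 NIP lines, 8 had a called rise, the smallest with a log2 fold change of 1.04 in RNAi-OsYTHDF2C. In osythdf1c it stood at 0.499 ± 0.13 CPM and in osythdf3b at 0.555 ± 0.24 CPM, and neither difference from NIP passed the test.

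The labelled backgrounds were compared with the expressed genes. A gene was counted as on in a group when every library had at least 1 CPM, and as off when every library had at most 3 counts. With 2 libraries in place of 3, osythdf2a meets either state more easily. Of 236 genes on in the NIP wild type and off in the DJ wild type, 6 were on in osythdf1a, 13 in osythdf2a and 6 in osythdf3a. In the 10 lines labelled NIP, between 114 and 162 of these genes were on. The opposite class held 504 genes, on in DJ and off in NIP. Of these, 401 were on in osythdf2a, 152 in osythdf1a and 176 in osythdf3a. In the 10 lines labelled NIP the number ranged from 35 in osythdf3b to 282 in RNAi-OsYTHDC1A. The NIP lines osythdf1b (265) and osythdf3c (247) also had more of these genes on than osythdf1a and osythdf3a.

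The wild types themselves differed widely. Of 28833 genes tested, 10865 were higher and 10782 lower in DJ than in NIP, and 5804 and 4295 of these differed at least 2-fold. LOC_Os10g22630 was at 467 ± 9.6 CPM (SD, n = 3) in DJ and at 0.115 ± 0.05 CPM in NIP (log2 fold change 11.62, SE 0.09). LOC_Os04g11120 was at 20.5 ± 1.1 CPM in DJ and had no counts in NIP, at least 476-fold higher when 3 counts over the NIP group are taken as the floor. In the other direction, LOC_Os12g12140 was at 45.6 ± 3.4 CPM (SD, n = 3) in NIP and without counts in DJ, at least 809-fold lower. LOC_Os09g04360 was at 33 ± 1.4 CPM in NIP and at least 585-fold lower in DJ. The largest adjusted p among these 4 genes was 3.9e-42 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All libraries were counted on the same genome build, and sequence variants were not analysed. For a gene without counts in 1 wild type, low expression and a differing or missing sequence therefore cannot be told apart. Library totals in place of TMM gave 14385 genes higher and 7451 lower in edgeR, and the authors' FPKM, also scaled by library totals, 13426 and 7139 in limma. Because of this difference between the wild types, each line was compared with the wild type of its labelled background.

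**Figure D1:**
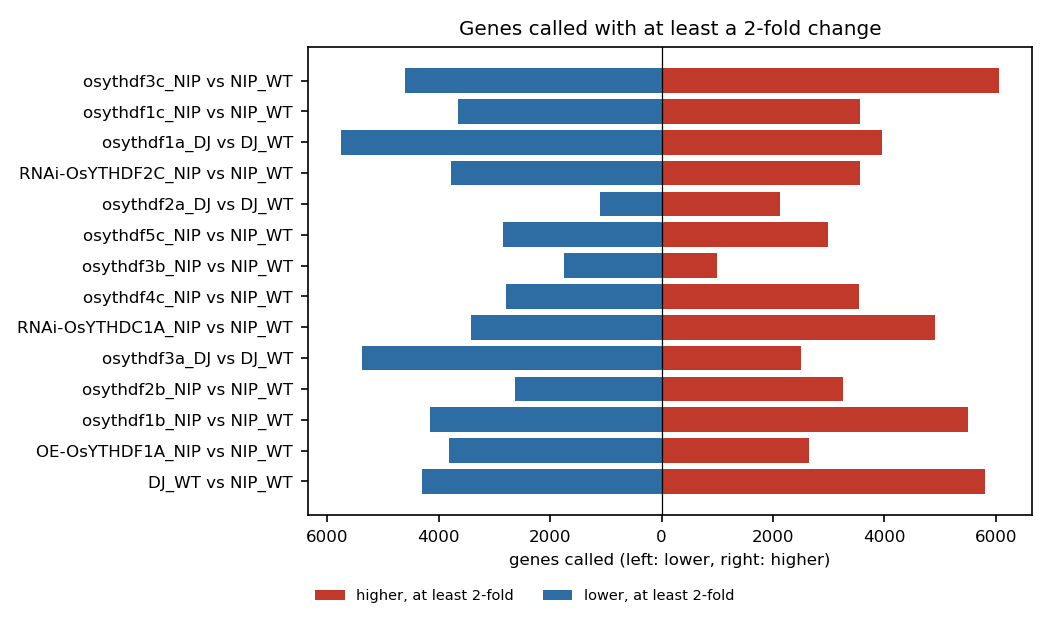
Genes called with at least a 2-fold change in each comparison, on a horizontal axis of gene counts with genes higher in the first-named group to the right and genes lower to the left. The bars reach 6061 genes higher and 4600 lower in osythdf3c, and 997 higher and 1752 lower in osythdf3b.

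Most genes tested differed between a line and its wild type. Over the 13 lines the share called ranged from 40% in osythdf3b to 78.5% in osythdf3c, with a median of 68.7%, and the share that also changed at least 2-fold ranged from 9.97% to 38.6%. Replicates lay close together: over 12794 well expressed genes the median SD between libraries of a NIP group was 0.079 on the log2 scale, whereas the means of the 11 NIP groups had a median SD of 0.35. When the groups themselves were taken as the units, with 1 summed library each and the line set against all other groups of its background, edgeR called between 0 and 28 genes per line, and 0 of them were lower in the line. Scaling by the library total in place of TMM shifted all genes of a comparison by between -0.26 (osythdf3a) and 0.31 (RNAi-OsYTHDC1A) on the log2 scale. In the same edgeR test with the same filter, it moved the share of higher genes among those called by over 10 percentage points in 11 of 14 comparisons. These splits are given beside the main ones as library totals, together with those of limma on the authors' FPKM, where the test and the filter differ as well.

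Among the NIP knockouts, osythdf3c differed most from the wild type, with 11528 genes higher and 10135 lower of 27584 tested. LOC_Os01g62740 rose from no counts to 15.4 ± 0.57 CPM (SD, n = 3) and LOC_Os04g09390 to 14.4 ± 1.7 CPM, at least 358-fold and 335-fold higher. LOC_Os12g12140 fell from 45.6 ± 3.4 CPM to no counts, at least 857-fold lower, and LOC_Os12g13360 from 31.5 ± 1 CPM, at least 592-fold lower. The line osythdf1b was close in number, with 10877 genes higher and 10341 lower. LOC_Os04g09390 rose there to 36.9 ± 3.3 CPM and LOC_Os02g52710 to 32.5 ± 1.2 CPM, both from no counts and at least 858-fold and 755-fold higher. The lowest fitted log2 fold changes under the naming rule in osythdf1b were those of LOC_Os12g12140, at least 912-fold lower, and LOC_Os12g17400, from 18.7 ± 1.1 CPM and at least 374-fold lower. At no counts this order rests on the fit, so other loci may have fallen further. Across these 8 results the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 5.8e-29. Library totals gave 14627 genes higher and 7494 lower in osythdf3c, and 13711 and 7748 in osythdf1b. The FPKM gave 13648 and 7188, and 12792 and 7382.

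In osythdf4c, 9815 genes were higher and 8607 lower than in NIP. LOC_Os07g26100 rose from 3 counts over the NIP group to 46.1 ± 2.2 CPM (SD, n = 3), a ratio of 1070 with a 95% counting interval from 366 to 5190. LOC_Os12g12690, higher in all 10 NIP lines, rose from 0.0567 ± 0.064 to 38.6 ± 2.7 CPM. LOC_Os11g09590 fell from 71.4 ± 3.3 CPM and LOC_Os05g46480 from 55.5 ± 2.6 CPM, each to 1 count over the group, with ratios of 4040 (95% counting interval from 725 to 160000) and 3140 (564 to 124000). These 4 fitted log2 fold changes depended on single libraries: LOC_Os07g26100 went from 9.72 to 10.55 without NIP replicate 2 and LOC_Os12g12690 from 9.09 to 10.28 without NIP replicate 1. Without osythdf4c replicate 2, LOC_Os11g09590 went from -11.67 to -13.53 and LOC_Os05g46480 from -11.31 to -13.16. In osythdf2b, 9151 genes were higher and 8784 lower. LOC_Os06g35510 rose from no counts to 16 ± 1.9 CPM, at least 373-fold, and LOC_Os05g45160 to 11.1 ± 0.18 CPM, at least 259-fold. LOC_Os12g12140 fell at least 819-fold and LOC_Os06g39090, from 18 ± 0.85 CPM, at least 323-fold. Library totals gave 12493 genes higher and 6640 lower in osythdf4c, and 11614 and 6635 in osythdf2b. The FPKM gave 11678 and 6369, and 10799 and 6337.

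The line osythdf1c had 9636 genes higher and 9325 lower. LOC_Os09g09210 rose from 1 count over the 3 NIP libraries to 55.2 ± 1.4 CPM (SD, n = 3), a ratio of 3840 with a 95% counting interval from 689 to 152000, and no other group exceeded a mean of 0.131 CPM. Its fitted log2 fold change was 11.37, and 13.12 without NIP replicate 2, which held the count. LOC_Os02g17260 rose to 11.5 ± 0.9 CPM, at least 267-fold. LOC_Os12g12140 and LOC_Os12g13360 again fell to no counts, at least 803-fold and 555-fold. In osythdf5c, 8725 genes were higher and 8550 lower. LOC_Os05g25570 rose to 19.7 ± 1.4 CPM and LOC_Os12g13445 to 9.23 ± 2.5 CPM, at least 457-fold and 212-fold. LOC_Os12g12140 fell at least 656-fold there and LOC_Os12g17400, from 18.7 ± 1.1 CPM, at least 269-fold.

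The line osythdf3b had the fewest called genes of the 13 lines, with 5472 genes higher and 5550 lower, of which 997 and 1752 changed at least 2-fold. The largest rise was that of a feature without a locus ID, at 190 ± 3.1 CPM (SD, n = 3) in this line and at 0.0721 ± 0.026 CPM in NIP (log2 fold change 11.33, SE 0.14), and no other group exceeded a mean of 0.158 CPM. LOC_Os08g08130 rose from 1 count over the NIP group to 11.9 ± 0.82 CPM, a ratio of 827 with a 95% counting interval from 148 to 32700. LOC_Os12g12690, higher in all 10 NIP lines, rose to 36.2 ± 0.91 CPM. The log2 fold changes of these loci were 9.26 and 9.23, and became 11.01 without NIP replicate 3 and 10.42 without NIP replicate 1. LOC_Os12g17400 fell at least 405-fold to no counts, and LOC_Os11g09590 to 2 counts, a ratio of 2320 with an interval from 643 to 19200. With the mean of the other 9 NIP lines as the reference in place of the wild type, 20141 genes were called in osythdf3b. Library totals gave 3794 genes higher and 7286 lower, and the FPKM 3353 and 6570.

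Knockdown by RNAi gave changes of similar extent. In RNAi-OsYTHDC1A, 10679 genes were higher and 9684 lower than in NIP. LOC_Os04g11120 rose from no counts to 33.5 ± 0.11 CPM (SD, n = 3) and LOC_Os01g19694 to 25.9 ± 0.41 CPM, at least 778-fold and 602-fold. LOC_Os12g13360 fell at least 662-fold and LOC_Os12g17400 at least 393-fold. With library totals 15389 genes were higher and 6171 lower, and with the FPKM 14177 and 5914. In RNAi-OsYTHDF2C, 9490 genes were higher and 9472 lower. LOC_Os12g24050 rose to 6.97 ± 0.87 CPM and LOC_Os07g39450 to 6.71 ± 0.77 CPM, at least 162-fold and 156-fold. LOC_Os12g17400 fell at least 370-fold and LOC_Os06g39090 at least 355-fold.

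Overexpression of OsYTHDF1A was measured in the NIP background, where 8867 genes were higher and 8603 lower. A feature without a locus ID rose from 3 counts over the NIP group to 136 ± 1.5 CPM (SD, n = 3), a ratio of 3170 with a 95% counting interval from 1080 to 15400. Its fitted log2 fold change was 11.58, and 12.41 without NIP replicate 2. LOC_Os12g12690, higher in all 10 NIP lines, rose from 0.0567 ± 0.064 to 34.6 ± 6.1 CPM. Its log2 fold change of 9.22 (SE 0.33) became 10.41 without NIP replicate 1. LOC_Os12g11830, also higher in all 10 NIP lines, rose from 2 counts to 17.9 ± 1.2 CPM, a ratio of 624 with an interval from 172 to 5160. LOC_Os12g12140 fell at least 825-fold and LOC_Os12g17400 at least 338-fold. Of all 15 groups this line had the largest mean share of counts in its 10 most abundant genes, 8.89% ± 0.14 (SD, n = 3), against 5.91% ± 0.067 in NIP. With library totals 6755 genes were higher and 10945 lower, and with the FPKM 6311 and 10365.

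In the DJ background, osythdf1a had 10096 genes higher and 10646 lower of 26925 tested, of which 3963 and 5763 changed at least 2-fold. LOC_Os08g27870 rose from 2 counts over the DJ group to 15.9 ± 1.3 CPM (SD, n = 3), a ratio of 423 with a 95% counting interval from 117 to 3500, and its fitted log2 fold change of 8.71 became 11.31 without DJ replicate 1. LOC_Os01g57968 stood at 700 ± 190 CPM against 0.391 ± 0.35 CPM in DJ (log2 fold change 11.09, SE 2.42, adjusted p = 0.0036 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without DJ replicate 1 its log2 fold change was 12.04, with an adjusted p of 0.017 in the same edgeR test with Benjamini-Hochberg adjustment. This locus varied between replicates elsewhere too. LOC_Os01g22380 fell from 15 ± 2.2 CPM and LOC_Os09g28200 from 14.1 ± 1.9 CPM, both to no counts and at least 276-fold and 259-fold lower. Library totals gave 7256 genes higher and 13350 lower, and the FPKM 6749 and 12298.

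The line osythdf3a had 9412 genes higher and 10024 lower than DJ. A feature without a locus ID stood at 1360 ± 110 CPM (SD, n = 3), against 0.0928 ± 0.028 CPM in DJ and at most 0.656 CPM as the mean of any other group (log2 fold change 13.96, SE 0.07). LOC_Os10g20280 rose from no counts to 29.2 ± 3.2 CPM and LOC_Os11g01310 to 25.6 ± 2.1 CPM, at least 520-fold and 458-fold. LOC_Os04g11110 fell from 26.7 ± 1.5 CPM and LOC_Os04g11120 from 20.5 ± 1.1 CPM, at least 468-fold and 359-fold. Replicate 3 of osythdf3a stood apart from replicates 1 and 2. The neighbouring loci LOC_Os09g00999 and LOC_Os09g01000, picked after their values were seen, took 12.5% of its counts, against 0.352% and 0.466% in the other 2 libraries. Without that library 18894 genes were called in place of 19436. With library totals 5997 genes were higher and 13197 lower, and with the FPKM 5584 and 12274.

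In osythdf2a, with 2 libraries, 5627 genes were higher and 8329 lower than in DJ, while among changes of at least 2-fold 2125 genes were higher and 1101 lower. In a fit of osythdf2a and DJ alone, with the same edgeR test and TMM, 6952 genes were higher and 6672 lower. Library totals gave 6638 and 4886, and the authors' FPKM 5673 and 4322. LOC_Os10g40240 rose from no counts to 29.7 ± 0.89 CPM (SD, n = 2) and LOC_Os10g20280 to 18.2 ± 0.93 CPM, at least 526-fold and 324-fold. LOC_Os01g49050 fell from 12 ± 1 CPM to no counts, at least 147-fold, and LOC_Os10g24004 from 49.6 ± 0.97 to 0.166 ± 0.033 CPM (log2 fold change -8.28, SE 0.19).

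The DJ lines osythdf1a and osythdf3a changed many of the same genes. Among changes of at least 2-fold, 4604 genes were lower in both lines and 1680 higher in both, while 91 moved in opposite directions. Independent lists of these sizes would share 1151 lower and 370 higher genes. Over 26925 genes the log2 fold changes had a correlation of 0.82 across genes, which are not independent replicates, and a covariance of 2.36. Unchanged groups, simulated together with their common DJ libraries, gave a correlation of 0.50 and a covariance of 0.0333. They shared no such calls, which is no measure for the shared genes, since the simulation held no change to call. The pairs with osythdf2a had correlations of 0.28 and 0.35, below the simulated 0.46 and 0.45, and covariances of 0.494 and 0.502 above the simulated 0.0339 and 0.0348. All 3 lines were compared with the same 3 control libraries, so whatever sets the DJ group apart enters each comparison. Independent lists and the simulation do not cover this, and the shared genes alone do not show a common response of the lines.

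**Figure D2:**
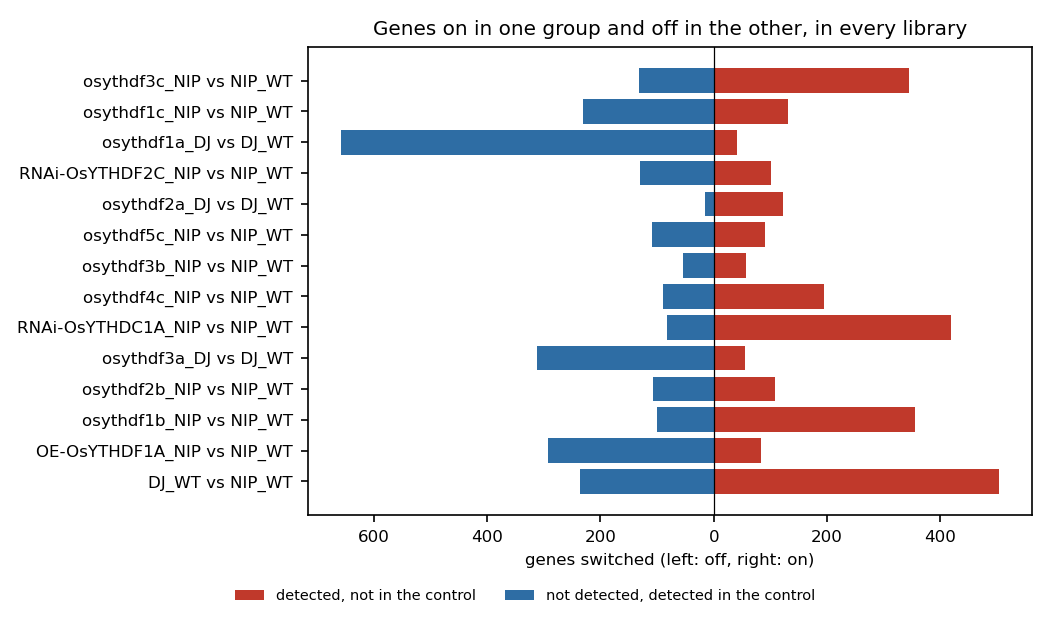
Genes on in every library of the first-named group and off in every library of its control (right) or the reverse (left), as counts of genes, where on means at least 1 CPM and off at most 3 counts. In osythdf1a 42 genes were switched on and 659 off; in RNAi-OsYTHDC1A 419 were switched on and 83 off.

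Genes that switched between detected and not detected differed in number and direction between the lines, and these differences between lines were not tested. In osythdf1a, 659 genes on in DJ were off and 42 were newly on, and in osythdf3a these numbers were 312 and 56. The overexpression line had 293 genes off and 84 on, and osythdf1c 231 off and 132 on. Most switches went the other way in RNAi-OsYTHDC1A, with 419 on and 83 off, in osythdf1b, with 355 on and 100 off, in osythdf3c, with 345 on and 132 off, in osythdf4c, with 195 on and 89 off, and in osythdf2a, the remaining DJ line, with 123 on and 16 off. RNAi-OsYTHDF2C had 102 on and 131 off, osythdf5c 90 on and 109 off, osythdf2b 109 on and 108 off, and osythdf3b 57 on and 54 off.

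The 10 NIP lines shared changes against their common wild type. In all 10 lines 441 genes were higher and 737 lower, where independent lists of the same sizes would share 1 and 0. Unchanged groups shared 0 when they and their common NIP libraries were simulated together. This 0 is no measure for the 441 and 737 genes. Such groups had on average only 0.333 genes called higher and 1.67 called lower in at least 1 line. Of the genes lower in all lines, LOC_Os12g12140 stood at 45.6 ± 3.4 CPM (SD, n = 3) in NIP and at no more than 0.0312 CPM in any line, and LOC_Os12g17400 at 18.7 ± 1.1 CPM and no more than 0.0202 CPM. Of those higher in all lines, LOC_Os06g38890 had no counts in NIP and between 1.9 and 7.64 CPM in the lines, and LOC_Os12g11660 no counts and between 1.93 and 10.2 CPM. LOC_Os12g12690 and LOC_Os12g11830, named above for single lines, were also higher in all 10 lines (24.6 to 38.6 and 9.92 to 17.9 CPM). LOC_Os11g09590 and LOC_Os06g39090 were also lower in all 10, at no more than 0.165 and 0.0462 CPM. The log2 fold changes of the 45 pairs of lines had a median correlation of 0.55 across genes, from 0.18 to 0.86, beside 0.45 in the simulation. Their median covariance was 1.29, beside 0.056 in the simulation. The pair with the highest correlation was RNAi-OsYTHDC1A and osythdf1b, at 0.86. All 10 comparisons subtract the same NIP libraries, so whatever sets the NIP group apart enters every one of them. The simulation holds only the noise of the libraries. Independent lists are therefore no measure here either, and the shared changes and correlations do not show a common response of the lines. With the mean of the other lines as the reference, 0 genes were called the same way in all 10 lines, which holds by construction, since no gene can lie above the mean of the others in every line.

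**Figure D3:**
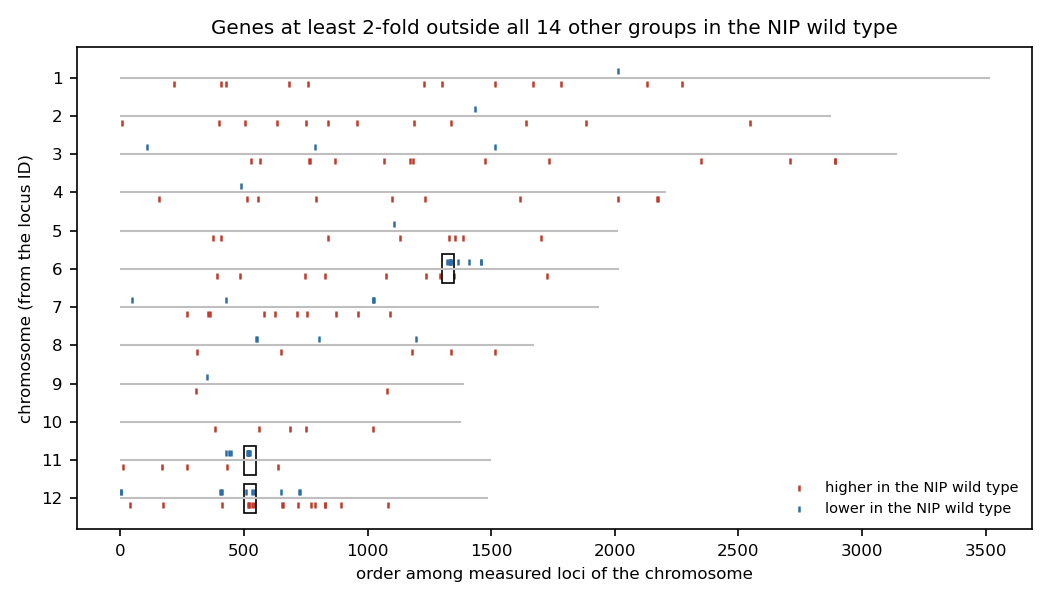
Loci at least 2-fold above (red) or below (blue) all 14 other groups in the NIP wild type, by chromosome and by order among the measured loci of that chromosome. Boxes mark the 3 windows of 50 neighbouring loci past the threshold, on chromosomes 6, 11 and 12.

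Several of these genes are neighbours. Chromosome and order were read from the locus IDs. Of 25078 measured loci, 157 lay at least 2-fold above or below every other group in the NIP wild type. In windows of 50 neighbouring loci, 3 windows held more such loci than chance (hypergeometric test, Benjamini-Hochberg adjustment over all windows and groups). The window on chromosome 12 from LOC_Os12g11680 to LOC_Os12g13110 held 8 (adjusted p = 6.4e-06). The windows on chromosome 6, from LOC_Os06g37610 to LOC_Os06g39120, and on chromosome 11, from LOC_Os11g11320 to LOC_Os11g13500, held 7 each (adjusted p = 6.6e-05 for both). In each of the other 14 groups 0 of 501 windows passed. The number of private genes was not particular to NIP. Over all features NIP had 120 above and 55 below every other group, osythdf2a 390 and 15, osythdf1a 214 and 137, and osythdf3c 187 and 134. The remaining groups had fewer in total than NIP. With the grid moved by 25 loci, or with windows of 25 loci, 2 windows passed, on chromosomes 6 and 11, and none on chromosome 12. Windows of 100 loci gave 3, on chromosomes 6, 11 and 12. Without the minimum of 1 CPM, as in the first scan of these data, 193 loci were private and 5 windows of 50 passed, on the same 3 chromosomes. Among the 11 NIP groups alone, 204 loci were private to NIP and 5 windows passed, 1 on chromosome 6, 1 on chromosome 11 and 3 on chromosome 12, and 1 window passed in RNAi-OsYTHDC1A. Counted over whole chromosomes, chromosome 12 held 28 private loci of 1483 (1.89%, adjusted p = 1.8e-06, hypergeometric test with Benjamini-Hochberg adjustment over 12 chromosomes). Chromosomes 6 and 11 held 19 and 15 (adjusted p = 0.19 for both in the same hypergeometric test with Benjamini-Hochberg adjustment). The window loci were picked by this scan after the values were seen.

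The last comparison set overexpression of OsYTHDF1A against the osythdf1a knockout. Of 26040 genes tested in both, 4519 were higher in both and 4396 lower in both, where independent lists would share 3256 and 3236. Opposite changes were fewer than independent lists would give, with 2391 genes higher on overexpression and lower in the knockout (3454 for independent lists) and 2361 the reverse (3051). The log2 fold changes had a Pearson correlation of 0.35 and a Spearman correlation of 0.28 across genes, which are not independent replicates. The lines have different backgrounds and different control libraries. Among changes of at least 2-fold, 837 genes were higher in both, 1934 lower in both, and 447 and 382 moved in opposite directions.

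**Figure D4:**
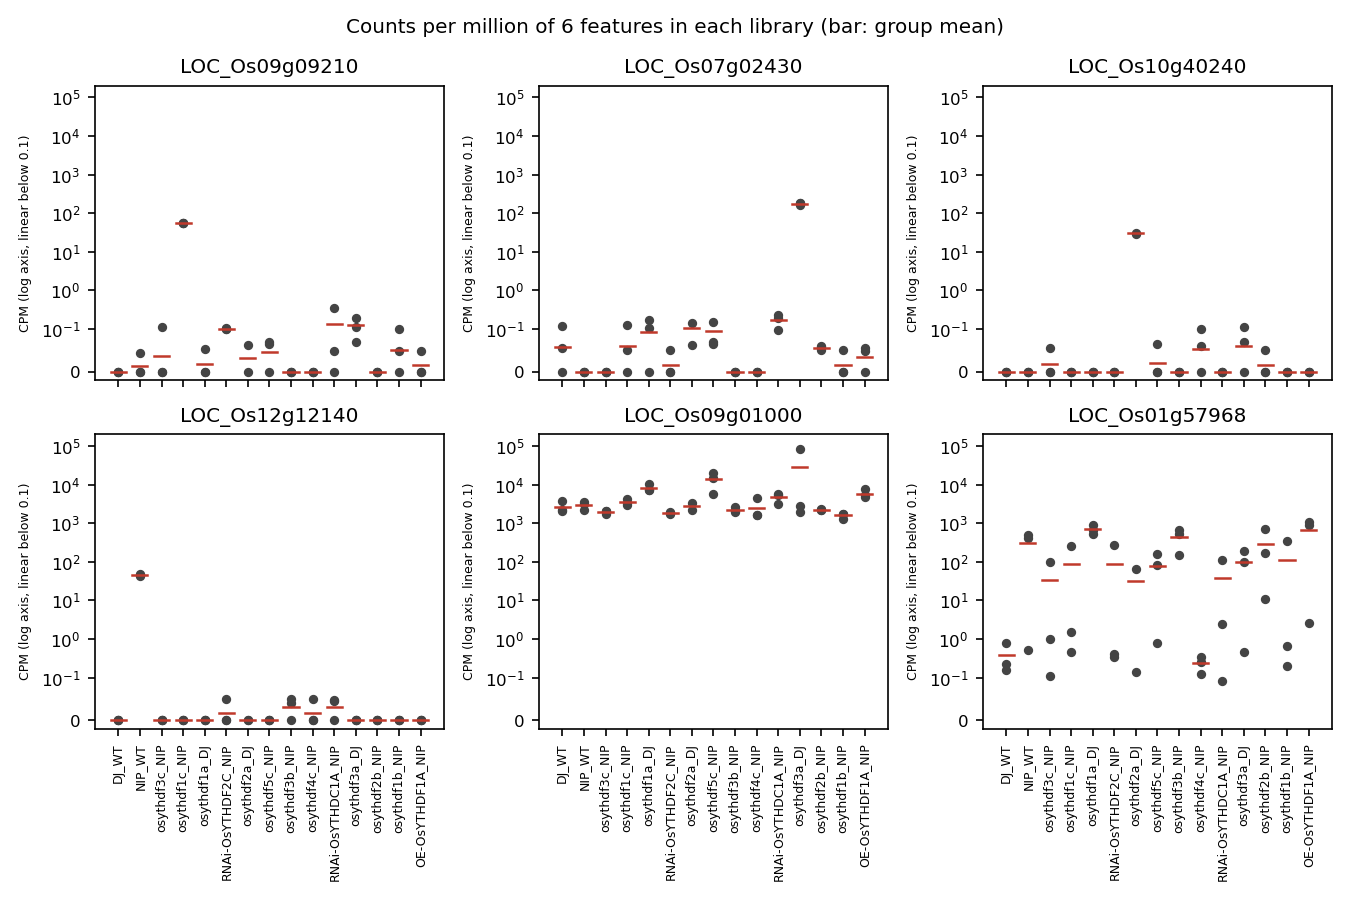
CPM of 6 features in each library, with a bar at the mean of each group; the vertical axis is logarithmic above 0.1 and linear below. LOC_Os09g09210 in osythdf1c, LOC_Os07g02430 in osythdf3a, LOC_Os10g40240 in osythdf2a and LOC_Os12g12140 in the NIP wild type stand above all other groups, LOC_Os09g01000 is high in osythdf3a replicate 3, and LOC_Os01g57968 varies between libraries of the same group.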

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

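Groups as units, library totals in edgeR, the gene length correction, the window choices, the removal of a shared component and the thinning were chosen after seeing the data. For the 13 lines and the wild types, counts of called genes stayed within 1.5 times the main ones in several settings. These were DESeq2 size factors, no filter, DESeq2, only the groups compared, log2(FPKM + 1), library totals and the length correction (lines alone). The same held for each of the 83 results with a replicate left out (9550 to 21237 genes), where 1 fit can give several results. The replicate numbers do not pair the samples: correlations of same-numbered libraries ranged from -0.21 to 0.14, 11 of 41 libraries lay closest to their own number, and the replicate block gave 10958 genes in osythdf3b and 13636 in osythdf2a. With 2-fold as the minimum, the counts were 10661 (osythdf3c), 7217 (osythdf1c), 9726 (osythdf1a), 7356 (RNAi-OsYTHDF2C), 3226 (osythdf2a), 5826 (osythdf5c), 2749 (osythdf3b), 6334 (osythdf4c), 8338 (RNAi-OsYTHDC1A), 7888 (osythdf3a), 5888 (osythdf2b), 9653 (osythdf1b), 6478 (OE-OsYTHDF1A) and 10099 (wild types), and 2771 genes went the same way in OE-OsYTHDF1A and osythdf1a, by construction fewer. With groups as units edgeR called 7 (osythdf3c), 28 (osythdf1c), 3 (RNAi-OsYTHDF2C), 4 (osythdf5c), 1 (osythdf3b), 2 (osythdf4c), 9 (RNAi-OsYTHDC1A), 2 (osythdf2b), 6 (osythdf1b) and 0 genes (OE-OsYTHDF1A, osythdf1a, osythdf2a, osythdf3a), none of them lower. At an unadjusted p under 0.05 the last 4 gave 1605, 1961, 671 and 356. With the other lines as reference, 20141 genes were called in osythdf3b, the cause of which was not tested, and 0 in all 10 NIP lines, which holds by construction. limma on log2(FPKM + 0.1) called 8636 genes in osythdf2a, and the cause was not tested. The correlation of OE-OsYTHDF1A with osythdf1a was 0.40 with the shared component removed and 0.58 with the other lines as reference, and the cause was not tested; thinning left 177 genes private to NIP in place of 175. The window scan gave 5 windows without the CPM minimum and 5 among the NIP groups alone in place of 3, and 2, 2 and 3 with other windows. For 72 pairs of a feature and a comparison (the first 2 each way, with and without a locus), 1201 values were obtained, with some features in several comparisons. Of these values, 1119 kept their direction and threshold and 82 their direction only, 59 with groups as units and 23 with the other lines as reference. The gene list tests, with their alternative correlation, were not run.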

Other observations

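The window scan and its other settings, the classes of switched genes and the tests on private genes were chosen after the patterns were seen. The same holds for the correlations of the first component, also without a library, the removal of a shared component, the length correction and classes and the groups as units. The test on DJ was chosen after its own result. Several features, also picked after their values were seen, were abundant in a single group. LOC_Os07g02430 stood at 176 ± 14.2 CPM (SD, n = 3) in osythdf3a and at no more than 0.173 CPM as the mean of any other group. LOC_Os08g14195 was at 96.4 ± 1.16 CPM in RNAi-OsYTHDC1A and at most 3.28 CPM elsewhere. LOC_Os02g03640 was at 68.1 ± 2.23 CPM (SD, n = 2) in osythdf2a and at most 2.04 CPM elsewhere. LOC_Os10g02880 was at 31.2 ± 0.674 CPM (SD, n = 3) in RNAi-OsYTHDF2C and at most 0.468 CPM elsewhere. In osythdf3a replicate 3, a feature without a locus ID reached 4900 CPM and no other library exceeded 67.4 CPM. LOC_Os01g57968 ranged from 0.0919 to 1100 CPM over the 44 libraries.

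The first principal component of the 15 group means held 40.2% of the variance over 23230 genes. Negative scores were those of osythdf3c (-122.3), DJ (-79.4), osythdf1b (-77.8), osythdf4c (-71.8), RNAi-OsYTHDC1A (-68) and osythdf2a (-64.6), and the highest was that of osythdf1a (105.1). Across the 15 groups the score rose with the share of counts in the 10 most abundant genes (Pearson r = 0.80, permutation p = 8e-05, adjusted 0.00024; Spearman rho = 0.85, permutation p = 0.0001, adjusted 0.0003; 3 measures tested, two-sided). Without osythdf3c and DJ, r was 0.72, and within the 11 NIP groups 0.78. The share of osythdf3a, 8.51%, rested on replicate 3, and without that library it was 4.6% and the relation had r = 0.75 (permutation p = 0.00056, adjusted 0.0017) and rho = 0.76 (permutation p = 0.0015, adjusted 0.0044). With any 1 library left out, r lay between 0.73 and 0.80. LOC_Os09g00999 and LOC_Os09g01000, high in that replicate, also took between 1.03% and 3.58% of counts in the osythdf5c libraries. The relation was not computed without these loci. The score fell with the number of genes detected in libraries thinned to the smallest library total (r = -0.68, permutation p = 0.0042, adjusted 0.0064, and rho = -0.66, permutation p = 0.0092, adjusted 0.014), with r = -0.67 without osythdf3c and DJ and -0.81 within NIP. The relation with the library total did not pass the test (r = -0.13, permutation p = 0.65, adjusted 0.65; rho = -0.28, permutation p = 0.31, adjusted 0.31), with r = -0.23 without the same groups and -0.16 within NIP.

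Of the 157 loci private to the NIP wild type, 7, 7 and 8 lie in windows of neighbouring loci on chromosomes 6, 11 and 12, and the others lie outside these windows, on all 12 chromosomes. Sequencing depth is argued against, since 3 windows still passed with every library thinned to the smallest total, and so is a mislabelled NIP_WT library, since of the genes private by 2 libraries, 100% showed the same state in the remaining one, in each rotation. Altered YTH gene dose in the lines stays open for the loci in windows. DJ, also a wild type, is on the side of the lines at the 157 loci by their definition. At the 41 loci in windows found among the 11 NIP groups alone it was so in 27 (65.9%, 95% binomial interval 49.4 to 79.9). Over all 204 loci private in that way, DJ was with the lines at 182 (89.2%, 95% binomial interval 84.1 to 93.1) and with NIP at 22. Altered gene dose alone would not put a wild type with the lines, so this weighs against it at most of the 204 loci. It is weak evidence, since the test was chosen after its own result and DJ differed from NIP at least 2-fold in 10099 of 28833 genes. How often DJ lay with the lines at other genes was not computed. A candidate explanation is that segments of the genome differ between the NIP wild type plants and the lines: among the other genes of the windows, NIP was the outermost of the 15 groups in 19.5%, against 11.8% elsewhere, 1.66 times as often (Fisher's exact test, two-sided, p = 0.012). Neighbouring genes are not independent, the clusters were known when this test was chosen in place of a circular one, the first scan, without the minimum of 1 CPM, gave 5 windows, a moved grid and windows of 25 loci gave 2, without chromosome 12, the 11 NIP groups alone gave 5, of which 3 on chromosome 12, and sequence variants were not analysed here, so this stays a hypothesis.

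Most genes tested were called, with a median of 18961 genes over the 13 lines. A gene length trend between libraries is argued against, since a length correction left a median of 19074 genes. With groups as units the median was 2 genes, but each test set 1 summed library against all other groups of its background, 0 genes were called lower in any line, and the spread between groups also holds the effects of the altered genes. The drop met the bound set for replicates that vary less than separately raised lines, but for these reasons, seen only after the value, it decides nothing and that explanation stays open. Each genotype was present as a single group, so conditions of growth or harvest and the effect of the gene cannot be told apart, and a biological effect of the YTH genes stays open.

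Fold changes of osythdf1a and OE-OsYTHDF1A went the same way more often than opposite ways, in 8915 against 4752 genes called in both. By their labels the first is a knockout and the second an overexpression line of the gene of that name. Other pairs of a NIP and a DJ line were not compared, so this is not shown to be particular to these lines. An axis of variation shared with the other groups is argued against as the whole cause, as far as a first component describes it. With that component removed the correlation was 0.40, against 0.35 before. The 0.58 with the other lines as reference does not bear on this, since a change of reference leaves such an axis in place. Genes that differ in length do not account for it, since the lowest correlation within 10 length classes was 0.31. Growth conditions shared by these lines and an effect common to loss and gain of the gene were not tested.

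For the 13 comparisons with 3 libraries in each group, the 6 libraries allow 10 splits, too few for a share under 0.05. In fits of the compared groups alone the real split called between 11936 (osythdf3b) and 21033 (osythdf3c) genes. It was the only 1 of the 10 splits with as many genes in each comparison, and the highest of the other splits called 1 gene in RNAi-OsYTHDF2C and 0 in the other 12.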
